A study of Mus musculus with 32 samples.

How the data were processed

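Bulk RNA from the lungs of C57BL/6 pups was sequenced in 32 libraries (stranded polyA selection), 4 for each of 8 groups, which were taken from the sample labels. The reads were demultiplexed with bcl2fastq 2.0 per the submitters' processing notes. The aligner, the genome build and the handling of strand are not given in the sources used here. The deposited files hold 46165 gene records per library with counts of exon, intron, gene and exon-exon reads, as total and as unique counts, made by the authors. The deposited files also hold TPM values computed by the authors, and per the file headers an expression value that is the RPKM. Only the counts were tested here. The RPKM equalled the expression value in every file and served only to derive the share of reads outside genes. The TPM values were not used. Total exon counts include reads that map to several places, and unique counts do not. In 18853 genes there was at least 1 exon read, and records without exon reads have reads only in the intron and gene columns. Coordinates are those of the files. Of 43003 gene IDs found in the RefSeq table of GRCm38.p6, 97.4% have a start within 5 kb of that table.

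The smallest library held 7918537 exon reads and the largest 12443221, the unique share was 87.5% to 90.9%, and 4.09% to 5.40% of reads lay outside genes. The 10 genes with most reads took 4.40% to 6.38%. Replicates were compared by a chi-square statistic per gene, which was 2.38 to 16.6 for every pair of a group, so no library was counted again within its group. Libraries of different groups were not compared in this way. The median SE of a log2 fold change was 0.0920 for daily saline against untreated and 0.0950 for tamoxifen against Miglyol.

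Total exon counts were fitted per age with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood F tests), and genes with a Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold, with no fold threshold. At each age all groups shared the estimate of the spread. CPM values (counts scaled to library size) are TMM-normalised and given as mean ± SD, and SE is the absolute log2 fold change divided by the square root of F. Main comparisons were daily saline against untreated, water against untreated, daily saline against water, each scrambled oligonucleotide against water, scrambled 1 against scrambled 2, Miglyol against saline and tamoxifen against Miglyol. Each scrambled oligonucleotide against untreated and tamoxifen against saline were additional. These choices were written down before the data were examined.

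In all, 52 gene lists of response pathways, developmental pathways, cell types and neighbouring tissues were written at the same time. Their tests used camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the lists of a comparison. For every list the members past the threshold over all genes and adjusted over the list alone were counted. One list had no gene in the files.

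Genes were named by a fixed rule. Among genes past the threshold with a mean of at least 1 CPM and CPM ranges that do not overlap, up to 10 of the largest rises and 10 of the largest falls were taken. Where fewer than 5 qualified, the 5 genes with the smallest p were added. Up to 4 members of each called list with the smallest p, and up to 4 members past the threshold of any other list described, completed the set. Predicted and clone names were passed over (7 in daily saline against water, 47 in Miglyol against saline, 21 in tamoxifen against Miglyol and 98 in tamoxifen against saline), as were Xist and Y-linked genes. Additional comparisons name only genes named elsewhere. Some genes that the rule selects are not reported here. A gene with under 90% unique reads is described as having shared reads.

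Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE scaling, other filters, unique reads, all reads in genes, a threshold of 1.5-fold, sex-linked genes left out, Xist as a covariate, only the 8 samples compared, all 32 in 1 fit, the replicate block, and each library left out. The intronic read share as a covariate, removal of the exon length trend, and the fit without water replicate 3 and with Xist were added after results were seen. All 35 splits of the 8 libraries of each comparison were refitted. On simulated counts edgeR found 74% of 100 genes changed 1.5-fold and 83% of 100 changed 2-fold for scrambled 2 against water (8 false among 181 called), and 76% and 90% for tamoxifen against Miglyol (15 false among 198). A further list of genes was shifted 1.5-fold in these counts, and its calls are among those called but not among the false ones.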

Results

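Lung transcriptomes of C57BL/6 mouse pups were measured in 32 libraries of polyadenylated RNA, 4 per group, to ask what injections, solvents and control compounds do on their own to gene expression in the growing lung. At postnatal day 14 there were 5 groups: untreated pups, pups given saline into the peritoneum every day from day 1 to day 13 (25 µl per g), pups given nuclease-free water on days 1 and 3 (10 µl per g), and 2 groups given a scrambled locked nucleic acid oligonucleotide (10 mg per kg, in that water, on the same days). Such oligonucleotides are used to block microRNAs, and the scrambled ones, scrambled 1 and scrambled 2, serve as their controls. At postnatal day 6 there were 3 groups, given 25 µl of saline, 25 µl of Miglyol (a triglyceride oil used as a vehicle) or 0.4 mg of tamoxifen in Miglyol on days 1 and 2. Tamoxifen binds the oestrogen receptor and is used to switch on inducible Cre recombinases.

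Each library held at least 7918537 exon reads, and 16211 to 16834 genes had reads. No replicate pair differed by so little that it could be 1 library counted again. Nothing in the labels ties each sample to a separate animal, so the p-values measure only the spread between these samples, which may be technical in part. Xist, the transcript of the silenced X chromosome, was high in 3 of the 4 untreated libraries, 2 each of the daily saline and scrambled 1 groups, 1 of scrambled 2, and 0 of the water group, whose 4 libraries were all high in Y-linked genes. At day 6 each group had 2 of each kind. The share of intronic reads, taken over genes that have exon reads, also differed between groups. It was 10.0 ± 1.04% in daily saline lungs (SD, n = 4 here and for every group below), 12.7 ± 1.95% in untreated, 14.1 ± 1.42% in water, and 13.9 ± 0.625% in scrambled 1 lungs, and ran from 11.1% to 13.8% in scrambled 2 lungs. At day 6 it was 15.1 ± 0.898% after saline, 13.1 ± 1.25% after Miglyol and 13.3 ± 1.33% after tamoxifen.

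**Figure D1:**
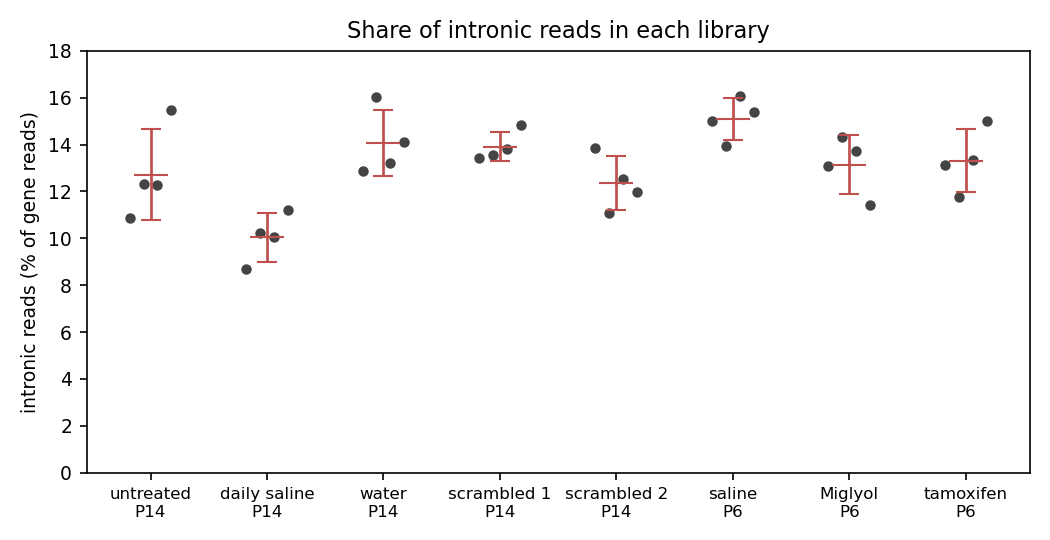
Intron reads as a share of gene reads, over genes that have exon reads (y axis, percent), in each library (dots), by group (x axis), with the group mean and SD in red. The daily saline libraries lie between 8.70% and 11.2%, and the P6 saline libraries between 13.9% and 16.1%.

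The number of genes past an adjusted p of 0.05 in edgeR ran from 0 for scrambled 2 against water to 3343 for tamoxifen against saline. Fixed lists of pathway and cell type genes were tested with camera beside the single genes. These list calls give directions only. All 87 list calls of the main comparisons were lost when the correlation between genes was estimated. In no comparison were more lists called than in every other split of the same 8 libraries.

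**Figure D2:**
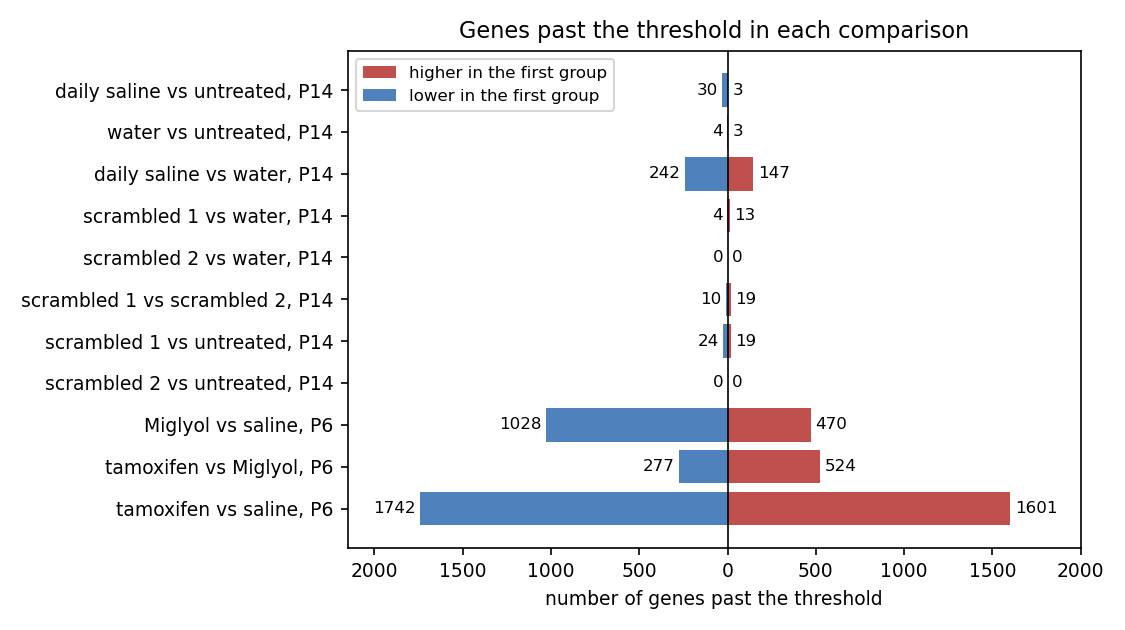
Number of genes past the threshold (x axis) in each comparison (y axis), with genes higher in the first-named group to the right in red and genes lower in it to the left in blue. Miglyol against saline gave 470 higher and 1028 lower genes, and scrambled 2 against water gave 0 and 0.

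Daily saline was first set against no intervention. In the daily saline lungs 30 genes fell and 3 rose, of 14179 tested, and none of these differences reached 1.5-fold. Clk4, a kinase of splicing factors, stood at 52.0 ± 2.59 CPM against 73.2 ± 3.26 in untreated lungs, a log2 fold change of -0.49 (SE 0.10, edgeR adjusted p = 0.0340). Luc7l3, a spliceosome component (gene ID 67684, chromosome 11, 94291139 to 94321983), stood at 182 ± 11.3 against 260 ± 30.8 CPM, though many of its reads map to more than 1 place. Prpf38b, also a splicing factor (gene ID 66921, chromosome 3, 108902807 to 108911752), fell by 0.42 (SE 0.06, edgeR adjusted p = 0.00220), from 176 ± 13.6 to 132 ± 4.18 CPM. Among the other leading falls were Ogt, the enzyme that adds N-acetylglucosamine to proteins, at -0.47 (SE 0.09), the p53 inhibitor Mdm4 at -0.43 (SE 0.08), Pnisr at -0.46 (SE 0.08), Rnpc3, a protein of the minor spliceosome, at -0.45 (SE 0.08), Arglu1 at -0.44 (SE 0.09), and Rbm4b and Prpf39 at -0.51 (SE 0.10) and -0.44 (SE 0.09). The last pair share reads with near copies. The 3 rises were Cat, the catalase gene, at 225 ± 10.2 against 185 ± 12.9 CPM (log2 0.28, SE 0.06), and Triobp and Pdzrn3 at 0.33 (SE 0.07) and 0.31 (SE 0.07), whose reads are largely not unique.

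Of the fixed lists, collagens and alveolar type 1 cells ranked higher in daily saline lungs. Of 22 collagen genes 20 lay above 0, with a median log2 of 0.13 and a camera adjusted p of 0.000298 (adjusted p = 0.975 with an estimated correlation), yet 0 passed over all genes in edgeR and 2 when adjusted over the list alone. Col4a1, a chain of basement membrane collagen, stood at 3411 ± 204 against 2915 ± 272 CPM (edgeR adjusted p = 0.214). In the list of alveolar type 1 cells, the flat cells of gas exchange, 13 of 14 genes lay above 0 with a median of 0.16 (camera adjusted p = 0.000298, 0.975 as adjusted p with an estimated correlation), and 0 passed over all genes and 5 adjusted over the list alone. Examples were Spock2 at 0.32 (SE 0.09) and Ager at 0.25 (SE 0.10). Only Prpf38b of the 13 genes named here by size stayed past the threshold in all 8 fits with 1 library left out, and the count fell to 1 without daily saline replicate 1 and to 9 without untreated replicate 1. With the intronic share as a covariate 0 genes passed in edgeR (1245 at an unadjusted p under 0.05), and the median of the 30 falls moved from -0.39 to -0.25, with a median SE of 0.0749 in both fits.

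**Figure D3:**
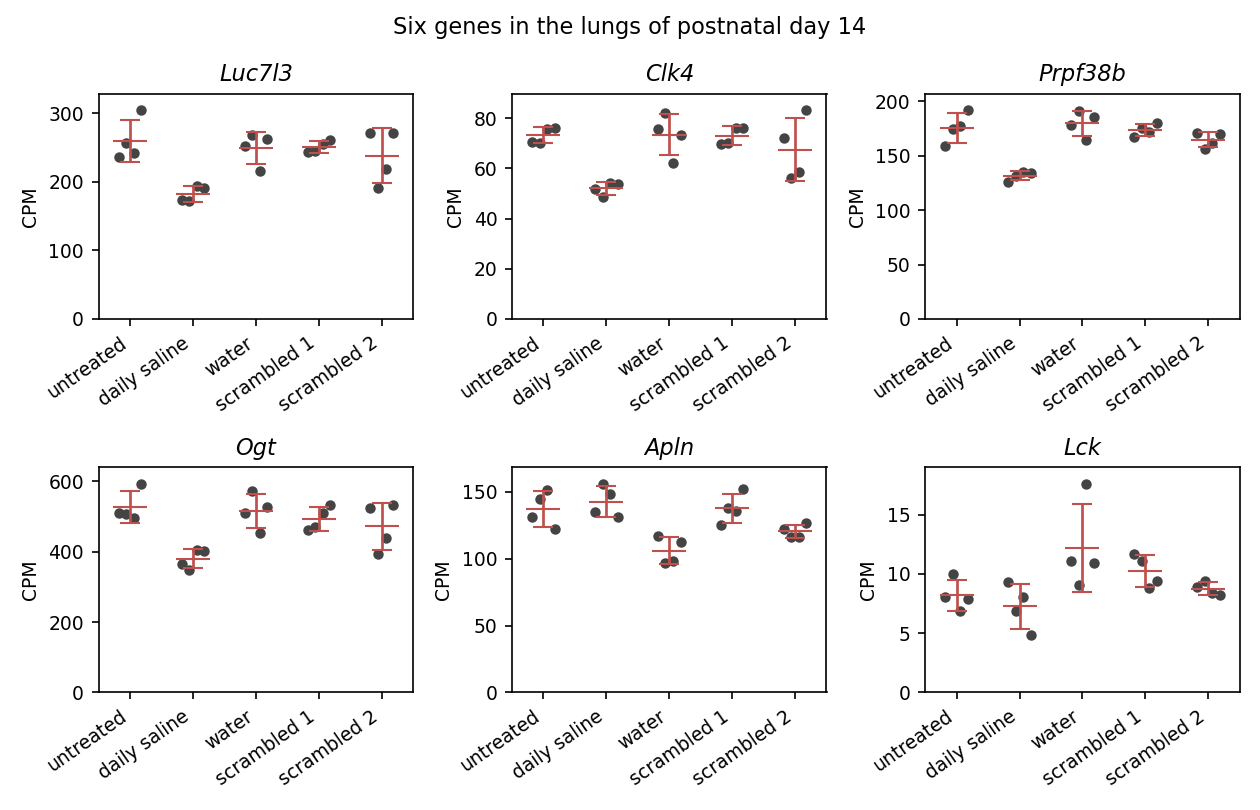
Normalised expression (y axis, CPM) of 6 genes in the 5 groups of postnatal day 14 (x axis), with each library as a dot and the mean and SD in red. Luc7l3, Clk4, Prpf38b and Ogt are lowest in daily saline lungs, Apln averages 106 CPM in water against 143 CPM in daily saline lungs, and 1 water library lies far above the others for Lck.

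Water was given as the solvent of the oligonucleotides, and its comparison with untreated pups asks what 2 solvent injections did. Only 7 genes passed in edgeR, 3 higher and 4 lower. Nox4, an NADPH oxidase (gene ID 50490, chromosome 7, 87246405 to 87398710), fell from 93.9 ± 3.74 to 72.7 ± 4.93 CPM (log2 -0.37, SE 0.06, edgeR adjusted p = 0.00699), and it alone passed in all 8 fits with 1 library left out. Neurl3, a ubiquitin ligase, fell by 0.90 (SE 0.16), the hyaluronan-binding Cemip by 0.60 (SE 0.10) and Sntg2 by 0.61 (SE 0.10). Gimap3, a GTPase of lymphocytes, rose by 0.53 (SE 0.09), the tight junction protein Cgn by 0.34 (SE 0.07) and Hmha1 by 0.31 (SE 0.06).

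Camera called 18 lists here. The aerocyte list, for the capillary cells of the gas exchange surface, ranked lower with 12 of 13 genes below 0 (camera adjusted p = 3.12e-05, and adjusted p = 0.463 with an estimated correlation), 0 past over all genes and 3 adjusted over the list alone. Its member Apln, a peptide of these cells, stood at 106 ± 9.91 against 137 ± 13.3 CPM (edgeR adjusted p = 0.0647). B cell genes and T and NK cell genes ranked higher, at median log2 values of 0.27 and 0.32 (camera adjusted p = 3.12e-05 and 8.95e-05, and adjusted p = 0.463 for both with an estimated correlation). In these lists 0 genes passed over all genes, and 4 of 14 and 3 of 17 passed when adjusted over the list alone. The T cell adaptor Lat lay at a log2 of 1.02 (SE 0.23). Water replicate 3 stood apart, with a mean log2 CPM of 4.99 over skeletal muscle genes, where the other water libraries had 0.799 to 1.28, and it was also the highest for adipose tissue and thymus genes. With Xist as a covariate 0 genes passed (edgeR, 1418 at an unadjusted p under 0.05, against 1147 without it). The median log2 fold change of the 7 genes moved little, from 0.343 to 0.365 among rises and from -0.608 to -0.560 among falls. Of the 35 splits of the 8 libraries 3 gave 7 genes or more. Without water replicate 1 the count was 1.

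Daily saline and water lungs were also compared directly. Rises and falls are given here for daily saline relative to water, and a difference may lie with either group. The direct comparison gave 389 genes, 147 higher and 242 lower in daily saline lungs. Cyp26b1, which breaks down retinoic acid (gene ID 232174, chromosome 6, 84571414 to 84593908), rose to 54.6 ± 18.0 from 23.3 ± 1.56 CPM (log2 1.22, SE 0.24, edgeR adjusted p = 0.0186). Next by size came Lhx6 (0.63, SE 0.17), Cemip (0.60, SE 0.10), Slfn3 (0.56, SE 0.11), the vasodilator peptide Adm (0.55, SE 0.12), the chondroitin synthase Chsy3 (0.54, SE 0.11), Lingo1 and Plac9b (0.51, SE 0.13, and 0.50, SE 0.11, both with shared reads), Gucy1a2, a subunit of the nitric oxide receptor (0.49, SE 0.09), and Prss35 (0.47, SE 0.08). The largest falls were those of Stac3 and Muc6, at -1.42 (SE 0.33 and 0.38) and about 1 CPM in daily saline lungs, Ankle1 (-1.30, SE 0.25), Nlrp1b, an inflammasome sensor (-1.27, SE 0.35), Ppargc1b, a coactivator of mitochondrial genes (-1.16, SE 0.25), Lat (-1.04, SE 0.23), Acaa1b (-0.90, SE 0.25), the formyl peptide receptor Fpr2 (-0.89, SE 0.22), and Spaca6 and Rasal3 (-0.87, SE 0.15 and 0.13). Ankle1, Acaa1b and Fpr2 share reads with near copies. Ppargc1b stood at 12.8 CPM in water replicate 3 and at 4.65 to 6.01 in the other water libraries, so part of its fall rests on that library. Of these 20 genes 4 passed in all 8 fits with 1 library left out, and 7 were lost in 5 or more.

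Vessel and mesenchymal lists lay on the side of daily saline. Among aerocyte genes 3 of 13 rose and 6 passed when adjusted over the list alone (camera adjusted p = 0.000297, and adjusted p = 0.461 with an estimated correlation). Apln rose by 0.43 (SE 0.08, edgeR adjusted p = 0.00639) and Itgb5 by 0.21 (SE 0.05), as did Ednrb, whose reads are mostly shared. In the list of general capillary cells 1 of 16 rose, the apelin receptor Aplnr (0.29, SE 0.06), and 3 passed when adjusted over the list alone (camera adjusted p = 0.00827, and adjusted p = 0.461 with an estimated correlation). All 17 genes of myofibroblasts and smooth muscle lay above 0 at a median of 0.17 (camera adjusted p = 0.000297, and adjusted p = 0.431 with an estimated correlation). Of them 1 rose, Aspn (0.39, SE 0.08, shared reads), and 5 passed adjusted over the list alone. In the TGF-beta and BMP list 2 of 24 rose, and 3 adjusted over the list alone (camera adjusted p = 0.00656, and adjusted p = 0.431 with an estimated correlation). They were Tgfb3, a ligand (gene ID 21809, chromosome 12, 86056743 to 86079041), at 185 ± 3.11 against 149 ± 9.58 CPM (edgeR adjusted p = 0.00668), and the endothelial receptor Acvrl1 (0.27, SE 0.07). Among matrix cross-linking enzymes 2 of 18 rose, the lysyl oxidases Lox (0.23, SE 0.06) and Loxl2 (0.27, SE 0.07, shared reads), and 3 adjusted over the list alone (camera adjusted p = 0.0165, and adjusted p = 0.461 with an estimated correlation). Camera did not call the list of alveolarisation growth factors (adjusted p = 0.162, 34 genes). In it Igfbp5 (0.38, SE 0.08), Wnt2 (0.43, SE 0.11) and the lymphatic receptor Flt4 (0.21, SE 0.06) rose, while Vegfa, the main endothelial growth factor, fell from 875 ± 53.1 to 673 ± 48.4 CPM (-0.38, SE 0.08).

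Lymphocyte lists lay on the side of water. Of 17 T and NK cell genes 4 fell, and 9 when adjusted over the list alone, at a median of -0.48 (camera adjusted p = 1.27e-05, and adjusted p = 0.431 with an estimated correlation). They were Lat, the kinase Lck at 7.26 ± 1.89 against 12.2 ± 3.74 CPM (edgeR adjusted p = 0.0309), Il7r, the receptor of interleukin 7 (-0.68, SE 0.17), and Cd4 (-0.79, SE 0.21). Of 14 B cell genes 3 fell, Cd22 (-0.45, SE 0.12) and Cd37 (-0.38, SE 0.10) among them, and 4 adjusted over the list alone (camera adjusted p = 0.00217, and adjusted p = 0.488 with an estimated correlation). In the circadian clock list 5 of 18 fell and 1 rose (camera adjusted p = 0.00834, and adjusted p = 0.431 with an estimated correlation), and 7 fell and 1 rose when adjusted over the list alone. The repressors Per2 and Per3 fell by 0.43 (SE 0.10) and 0.42 (SE 0.10) and Cry2, with shared reads, by 0.20 (SE 0.05), and their activator Arntl rose by 0.26 (SE 0.07). Of 27 cell cycle genes 25 lay below 0 (camera adjusted p = 0.000297, and adjusted p = 0.653 with an estimated correlation), yet 0 passed, with Mki67 at 83.9 ± 12.7 against 112 ± 11.8 CPM (edgeR adjusted p = 0.116). Skeletal muscle, thymus and adipose genes also lay lower, at medians of -2.39, -0.85 and -2.16 (camera adjusted p = 0.0134, 0.0276 and 0.0107, and adjusted p = 0.653, 0.619 and 0.653 with an estimated correlation), and water replicate 3 was the library that carried them. The count of genes was 28 without daily saline replicate 1 and 264 without water replicate 3 and with Xist as a covariate. With the intronic share as a covariate it was 13, the medians of the rises and falls moving from 0.27 to 0.26 and from -0.38 to -0.18.

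Scrambled 1 against water asks what the first control oligonucleotide added to its solvent. All comparisons with water share its 4 libraries, which were all high in Y-linked genes. Of the 17 genes past the threshold, 13 were higher and 4 lower. Slc17a2, a phosphate transporter (gene ID 218103, chromosome 13, 23806941 to 23825191), fell to 2.91 ± 0.364 from 7.18 ± 1.29 CPM (log2 -1.30, SE 0.18, edgeR adjusted p = 0.00272). Colq, the collagen tail of acetylcholinesterase (gene ID 382864, chromosome 14, 31523082 to 31577863), rose to 18.7 ± 1.56 from 11.0 ± 0.324 CPM (0.77, SE 0.12, edgeR adjusted p = 0.00538). Itih5, which binds hyaluronan, fell by 0.50 (SE 0.08). These 3 genes passed in all 8 fits with 1 library left out. Further rises were Hpcal4 (1.26, SE 0.25), Wisp2 (0.63, SE 0.13), the ethanol-metabolising Cyp2e1 (0.56, SE 0.11), extracellular superoxide dismutase Sod3 (0.50, SE 0.09), the chemokine Cxcl14 (0.48, SE 0.08), Disp2 (0.46, SE 0.09), the histone variant H2afj (0.46, SE 0.08), Ndufa4l2 (0.41, SE 0.08) and Apln (0.38, SE 0.08). Tgfbi, a matrix protein, and Egfem1, with shared reads, fell by 0.38 (SE 0.07 each).

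Aerocyte genes ranked higher than in water lungs (camera adjusted p = 6.29e-07, and adjusted p = 0.575 with an estimated correlation). Apln was 1 of 13 that passed over all genes, and 8 passed adjusted over the list alone. Apln averaged 138 CPM in scrambled 1, 137 in untreated, 143 in daily saline, 120 in scrambled 2 and 106 in water lungs. Its rise may therefore lie with the water group rather than with the oligonucleotide. Interferon response genes and antigen presentation genes lay above 0 in 22 of 27 and 16 of 18 cases (camera adjusted p = 0.00409 and 0.00428, and adjusted p = 0.912 for both with an estimated correlation), and 0 of them passed by either adjustment. Fatty acid oxidation and PPAR target genes lay below 0 in 19 of 21 cases, at a median of -0.24 (camera adjusted p = 0.00409, and adjusted p = 0.912 with an estimated correlation), and 0 fell over all genes. With Xist as a covariate the count was 2, and without scrambled 1 replicate 4 it was 3. With Xist the medians of the 17 genes hardly moved, from 0.461 to 0.459 among rises and from -0.438 to -0.442 among falls.

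Scrambled 2 against water asks the same of the other oligonucleotide. No gene passed in edgeR, where 755 genes had an unadjusted p under 0.05. DESeq2 called 5 genes and limma-voom 0. The 5 genes with the smallest p were Tmem201 (-0.40, SE 0.07, edgeR adjusted p = 0.147), Nox4 (0.28, SE 0.06), the cartilage protein Cilp (0.64, SE 0.13), Rasal3 (-0.63, SE 0.13) and Hmha1 (-0.28, SE 0.06), the last 4 at an edgeR adjusted p of 0.177. Camera called 10 lists. Aerocyte genes lay above 0 in 12 of 13 cases (camera adjusted p = 0.00415, and adjusted p = 0.827 with an estimated correlation), and T and NK cell genes below 0 in 16 of 17 (camera adjusted p = 0.0144, and adjusted p = 0.827 with an estimated correlation). By either adjustment 0 genes of both lists passed. Skeletal muscle genes, high in water replicate 3, had a median of -1.78 (camera adjusted p = 0.0156, and adjusted p = 0.827 with an estimated correlation). In simulated counts of this comparison, with 100 genes changed 1.5-fold, 100 changed 2-fold and a further list shifted 1.5-fold, 74% of the first were found. Changes of that size or smaller could therefore have been missed. With fewer changed genes the adjusted threshold is stricter, and the share found could be lower. The simulated counts also held no library set apart like water replicate 3, which could lower the share further.

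The control oligonucleotides were also compared directly, at the same dose and on the same days. Scrambled 1 lungs had 19 genes higher and 10 lower than scrambled 2 lungs. Colq (0.69, SE 0.12, edgeR adjusted p = 0.0156), H2afj at 37.9 ± 2.05 against 26.7 ± 3.10 CPM (edgeR adjusted p = 0.00827) and Ssbp4 (0.51, SE 0.08) were higher, as were the cytokine receptor Crlf2 (0.63, SE 0.12), Eva1b (0.56, SE 0.10), the endothelial transcription factor Sox18 (0.49, SE 0.09), Disp2 (0.47, SE 0.09), Ccdc85b (0.47, SE 0.10, shared reads), the lymphocyte kinase Jak3 (0.44, SE 0.09) and Pced1b (0.44, SE 0.09). Slc17a2 was lower (-1.17, SE 0.19, edgeR adjusted p = 0.00827), and so were Itih5 (-0.46, SE 0.08), Aspn (-0.42, SE 0.08, shared reads), Prss35 (-0.38, SE 0.08), Tgfbi (-0.37, SE 0.07), the matrix protein Thbs2 (-0.35, SE 0.07), Nceh1 (-0.33, SE 0.06), Loxl2 (-0.33, SE 0.07, shared reads), Cat (-0.28, SE 0.06) and the polarity kinase Prkci (-0.27, SE 0.06).

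Interferon response genes lay above 0 in 26 of 27 cases in scrambled 1 lungs (camera adjusted p = 5.01e-05, and adjusted p = 0.868 with an estimated correlation), antigen presentation genes in 18 of 18 (camera adjusted p = 5.08e-05, and adjusted p = 0.868 with an estimated correlation) and B cell genes in 13 of 14 (camera adjusted p = 0.00163, and adjusted p = 0.868 with an estimated correlation). Over all genes 0 of these passed, and adjusted over the list alone 4 B cell genes did. Irf7, a regulator of interferon genes, stood at 16.2 ± 1.05 against 12.7 ± 0.842 CPM (edgeR adjusted p = 0.301). The count was 0 without scrambled 1 replicate 1 and 205 without scrambled 2 replicate 4, and 17 of the 20 genes named here were lost in 5 or more of the 8 fits with 1 library left out. Another split of the same 8 libraries gave 600 genes.

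Set against untreated lungs, scrambled 1 gave 43 genes, 19 higher and 24 lower, and scrambled 2 gave 0 in edgeR, with 936 at an unadjusted p under 0.05, 4 in DESeq2 and 1 in limma-voom. Alveolar type 1 genes ranked higher after both (camera adjusted p = 2.02e-08 and 8.16e-10, and adjusted p = 0.412 and 0.627 with an estimated correlation), at medians of 0.22 and 0.21 with 14 of 14 genes above 0 in each. Over all genes 1 and 0 rose, and adjusted over the list alone 6 and 9. This list also ranked higher after daily saline. These comparisons share the same untreated libraries, so the rankings are not independent and may lie with the untreated group. B cell genes ranked higher after scrambled 1 at a median of 0.41 (camera adjusted p = 4.00e-09, and adjusted p = 0.321 with an estimated correlation), with 2 of 14 past over all genes and 8 adjusted over the list alone.

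At day 6, Miglyol was compared with saline at the same volume and on the same days, to show what the oil vehicle does. It gave 1498 genes, 470 higher and 1028 lower, of 14107 tested, most of them by little: the median size was 0.33 among rises and -0.34 among falls. Zbtb20, a transcriptional repressor (gene ID 56490, chromosome 16, 42875853 to 43621944), fell to 3.92 ± 1.09 from 13.4 ± 2.67 CPM (log2 -1.80, SE 0.22, edgeR adjusted p = 0.00181). Other large falls were Zfp366 (-1.54, SE 0.27), the potassium channel Kcna3 (-1.54, SE 0.36), Uprt (-1.40, SE 0.27), Psme2b (-1.31, SE 0.28, shared reads), Ago2, the slicing protein of the microRNA machinery, at 40.9 ± 12.6 against 95.3 ± 5.34 CPM, Atf7 (-1.13, SE 0.27), Glis3 (-1.08, SE 0.20) and Nbeal1 (-1.06, SE 0.23). The largest rises were the lipoxygenase Alox15 (1.45, SE 0.36, edgeR adjusted p = 0.0208), Ifitm6 (1.24, SE 0.31), Pi16 (0.93, SE 0.23), Gabra4 (0.89, SE 0.26) and Cyp4f18 (0.81, SE 0.19). Sapcd1, Gapdh, Chil3, Prr15 and Rpl10 also rose by 0.77 or more, but under 90% of their reads map to a single place. Of the 20 genes selected by size 7 passed in all 8 fits with 1 library left out, and 7 were lost in 5 or more, Ago2 among them.

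Cholesterol biosynthesis genes ranked higher after Miglyol, with 6 of 23 past over all genes and 9 adjusted over the list alone (camera adjusted p = 0.000110, and adjusted p = 0.825 with an estimated correlation). Msmo1, a sterol oxidase (gene ID 66234, chromosome 8, 64718145 to 64733578), rose to 34.8 ± 1.88 from 25.0 ± 1.75 CPM (edgeR adjusted p = 0.00954), and Insig1, Fdps and Idi1, all with shared reads, rose by 0.43 (SE 0.08), 0.39 (SE 0.08) and 0.34 (SE 0.09). All 36 cytoplasmic ribosomal protein genes lay above 0 at a median of 0.20 (camera adjusted p = 5.43e-06, and adjusted p = 0.825 with an estimated correlation), of which 4 rose, Rplp1 (0.32, SE 0.10, shared reads) among them, and 7 adjusted over the list alone. With the intronic share as a covariate their median was -0.01 with 0 past, and with the length trend removed it was -0.03 with 1 past. All 15 genes of club and secretory cells lay above 0, though only Scgb1a1, their main secreted protein, passed (0.32, SE 0.08), and 1 adjusted over the list alone (camera adjusted p = 0.00984, and adjusted p = 0.825 with an estimated correlation). All 11 neutrophil genes lay above 0 at a median of 0.95 (camera adjusted p = 0.00277, and adjusted p = 0.825 with an estimated correlation) and 0 passed by either adjustment, with S100a9 at 61.6 ± 9.11 against 27.8 ± 3.53 CPM (edgeR adjusted p = 0.0713) and Retnlg at a log2 of 2.17 (SE 0.63, edgeR adjusted p = 0.0553). Of 27 cell cycle genes 23 lay above 0 (camera adjusted p = 0.0155, and adjusted p = 0.957 with an estimated correlation), and 1, the replication clamp Pcna (shared reads), rose by either adjustment. Outside the called lists, the stress response genes Manf (0.43, SE 0.09) and Atf4 (0.29, SE 0.07) and the monocyte receptor Ccr2 (0.64, SE 0.15) rose.

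Camera ranked lists of growth factors, pericytes, capillary cells, collagens, TGF-beta and BMP signalling and the microRNA pathway lower. Of 34 alveolarisation growth factors 8 fell, also 8 adjusted over the list alone (camera adjusted p = 0.00277, and adjusted p = 0.617 with an estimated correlation). Among them were Ptch1, the hedgehog receptor (-0.37, SE 0.07, edgeR adjusted p = 0.00986), the growth factor receptors Pdgfra (-0.33, SE 0.07) and Pdgfrb (-0.22, SE 0.05), and Notch3 (-0.34, SE 0.08, shared reads). In the pericyte list 4 of 12 fell, including Itga8 (-0.37, SE 0.08) and Rgs5 (-0.58, SE 0.14), and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0170, and adjusted p = 0.617 with an estimated correlation). In the list of general capillary cells 4 of 16 fell, and 5 adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.617 with an estimated correlation). Of these Cd93 (gene ID 17064, chromosome 2, 148436651 to 148443535) stood at 487 ± 9.70 against 617 ± 16.6 CPM (edgeR adjusted p = 0.00913), and the junction proteins Cdh5 and Ptprb fell by 0.27 (SE 0.06) and 0.53 (SE 0.12). Collagens fell in 2 of 22 cases, Col6a3 (-0.47, SE 0.11) and Col4a1 (-0.27, SE 0.07), and in 8 adjusted over the list alone (camera adjusted p = 0.00879, and adjusted p = 0.825 with an estimated correlation). In the TGF-beta and BMP list Smad3 (-0.28, SE 0.06), Tgfbr2 (-0.23, SE 0.07) and Bmp5 (-0.40, SE 0.11) fell, 3 of 24 and 5 adjusted over the list alone (camera adjusted p = 0.0304, and adjusted p = 0.825 with an estimated correlation). Of 14 microRNA pathway genes 7 fell and 2 rose (camera adjusted p = 0.00984, and adjusted p = 0.825 with an estimated correlation), and 8 and 2 adjusted over the list alone. Ago3 (-0.55, SE 0.11) and Tnrc6c (-0.44, SE 0.09) fell and Tarbp2 (0.44, SE 0.09, shared reads) rose.

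Gene length went with the direction of change. The median exon length was 1578 bases among the rises, 7536 among the falls and 3472 among all genes tested, and Spearman's rho between exon length and log2 fold change was -0.615 across 14107 genes, which are not independent replicates. For tamoxifen against Miglyol that rho was 0.0763. Camera was not run with the length trend removed. Whether the lists ranked lower after Miglyol follow exon length was therefore not tested. The count was 357 with the length trend of each library removed, 2 with the intronic share as a covariate and 308 without P6 saline replicate 4. With the intronic share as a covariate the medians of rises and falls moved from 0.33 to 0.22 and from -0.34 to -0.21.

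**Figure D4:**
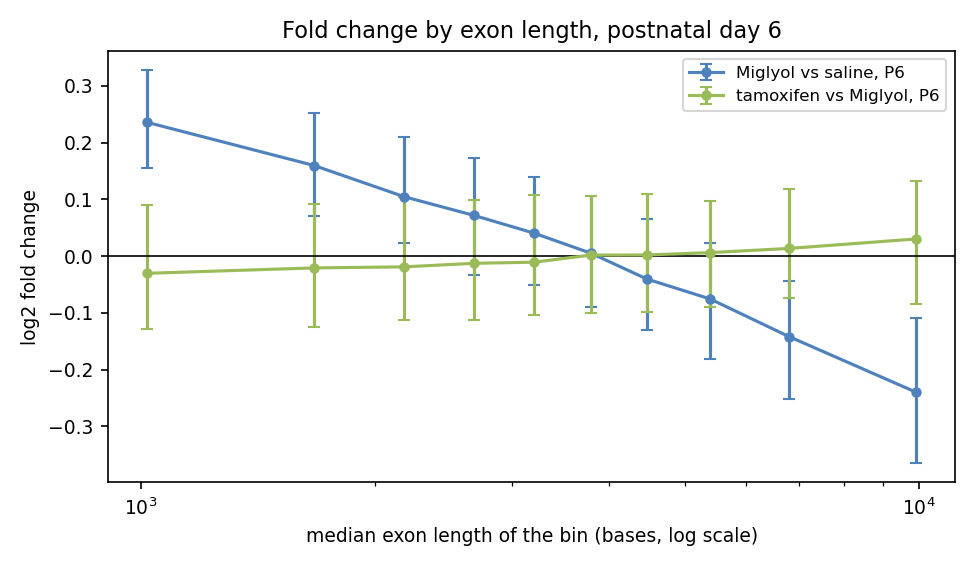
Median log2 fold change (y axis, with bars from the lower to the upper quartile of the genes) in 10 bins of genes by exon length (x axis, bases, log scale) at postnatal day 6. For Miglyol against saline it runs from 0.24 in the shortest to -0.24 in the longest genes, and for tamoxifen against Miglyol from -0.03 to 0.03.

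Tamoxifen was then compared with its own vehicle. It gave 801 genes, 524 higher and 277 lower. Their median absolute log2 fold change was 0.482, against 0.336 for Miglyol against saline, and the largest was 4.66 against 1.80. Gpnmb, a glycoprotein of lipid-laden macrophages (gene ID 93695, chromosome 6, 49036518 to 49058182), rose to 54.5 ± 36.3 from 3.93 ± 0.953 CPM (log2 3.79, SE 0.72, edgeR adjusted p = 0.0161), but 1 tamoxifen library lay near the Miglyol level. Prmt8, a protein methyltransferase of neurons, stood at 2.24 ± 0.902 CPM and was close to undetected in Miglyol lungs at 0.0752 ± 0.0522 (edgeR adjusted p = 0.000169). The agouti gene, a, which sets coat colour, rose by 3.28 (SE 0.32). Among the other large rises were the neutrophil granule and cytosol proteins Camp (2.55, SE 0.43), Ngp (2.43, SE 0.41), S100a8 (2.25, SE 0.34) and Ltf (2.21, SE 0.39), beside the protease inhibitors Stfa2 (2.40, SE 0.36) and Stfa3 (2.22, SE 0.34) and the protease Asprv1 (2.21, SE 0.31). The largest falls were Lmo3 (-2.33, SE 0.35), Thsd7b (-2.21, SE 0.22, edgeR adjusted p = 2.83e-05, gene ID 210417, chromosome 1, 129273304 to 130219278), Prokr2 (-2.06, SE 0.32), myoglobin, Mb, at 4.43 ± 2.24 against 18.3 ± 4.60 CPM, Slitrk6 at 18.0 ± 4.01 against 55.7 ± 13.1, the neuropeptide receptor Npy2r (-1.61, SE 0.26), the olfactory-type receptor Olfr78 (-1.49, SE 0.15), the glycine receptor subunit Glrb (-1.38, SE 0.28), Igfbp2 (-1.36, SE 0.13), which binds insulin-like growth factors, and Slc22a19 (-1.26, SE 0.29). Of these 20 genes 18 passed in all 8 fits with 1 library left out.

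Camera ranked several lists of immune cells and their products higher. Of 11 neutrophil genes 10 passed over all genes and 11 adjusted over the list alone, at a median log2 of 2.17 (camera adjusted p = 5.69e-14, and adjusted p = 0.178 with an estimated correlation). S100a9 (gene ID 20202, chromosome 3, 90692630 to 90695721) stood at 278 ± 116 against 61.6 ± 9.11 CPM and 27.8 ± 3.53 after saline, and Mmp9, a gelatinase, rose by 1.85 (SE 0.30). The neutrophil list averaged a log2 CPM of 4.29 in tamoxifen replicate 4 and 5.65 to 6.13 in the other tamoxifen libraries, where the Miglyol libraries had 3.51 to 3.81. Of the acute inflammation list 4 of 12 rose, and 7 adjusted over the list alone (camera adjusted p = 2.61e-06, and adjusted p = 0.178 with an estimated correlation), including Lcn2 (1.45, SE 0.20), Il1b, the interleukin 1 beta gene (1.74, SE 0.38), and Socs3 (0.50, SE 0.10). In tamoxifen replicate 4 this list too, and the lysosomal list below, lay close to the Miglyol libraries. In the list of alveolar macrophages 5 of 14 rose, and 5 adjusted over the list alone (camera adjusted p = 0.00317, and adjusted p = 0.323 with an estimated correlation), with Itgax (1.16, SE 0.24), Marco (0.68, SE 0.16) and, with shared reads, Chil3 (1.92, SE 0.18). Monocytes and interstitial macrophages had 4 of 16, C1qb among them (0.64, SE 0.14), and 8 adjusted over the list alone (camera adjusted p = 0.000270, and adjusted p = 0.223 with an estimated correlation). Lysosomal genes lay above 0 in 20 of 20 cases and 6 rose by either adjustment (camera adjusted p = 1.48e-06, and adjusted p = 0.381 with an estimated correlation), such as the proton pump subunit Atp6v0d2 (43.1 ± 16.4 against 15.2 ± 1.38 CPM), Cd68 (0.90, SE 0.20) and the cholesterol carrier Npc2 (0.39, SE 0.08). B cell genes had 2 of 13, Cd22 among them (0.58, SE 0.13), and 6 adjusted over the list alone (camera adjusted p = 8.92e-05, and adjusted p = 0.223 with an estimated correlation).

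Camera also ranked lists of epithelial cells and of glucocorticoid targets higher. Of 15 genes of club and secretory cells 6 rose, and 9 adjusted over the list alone, at a median of 0.67 (camera adjusted p = 4.68e-07, and adjusted p = 0.146 with an estimated correlation). Scgb1a1 (gene ID 22287, chromosome 19, 9083642 to 9087956) rose from 4180 ± 268 to 6728 ± 683 CPM (edgeR adjusted p = 0.000126), with haptoglobin, Hp (0.67, SE 0.08), and the cytochrome Cyp2f2 (0.53, SE 0.08). Of 18 genes of alveolar type 2 cells, which make surfactant, 6 rose, and 10 adjusted over the list alone (camera adjusted p = 1.48e-06, and adjusted p = 0.229 with an estimated correlation). Among them were Sftpa1 at 1784 ± 243 against 1188 ± 57.2 CPM, Sftpd (0.64, SE 0.10) and Lyz2 (0.50, SE 0.07), which macrophages also express. Mesothelial genes had 4 of 11, Msln among them (0.45, SE 0.06), and 4 adjusted over the list alone (camera adjusted p = 0.000834, and adjusted p = 0.323 with an estimated correlation). Of 15 glucocorticoid targets 9 rose, and 10 adjusted over the list alone (camera adjusted p = 2.49e-09, and adjusted p = 0.146 with an estimated correlation). Per1, which is also a clock gene (gene ID 18626, chromosome 11, 69095140 to 69109965), stood at 82.0 ± 10.6 against 39.5 ± 5.70 CPM (edgeR adjusted p = 9.48e-05), and Zbtb16 (1.40, SE 0.23) and Errfi1 (0.51, SE 0.08) rose with it. In the clock list 4 of 18 rose, with Per2 (0.45, SE 0.08) and Bhlhe40 (0.77, SE 0.14), and 5 adjusted over the list alone (camera adjusted p = 0.00585, and adjusted p = 0.146 with an estimated correlation). Immediate early genes had 3 of 18, Junb (0.51, SE 0.12) and Jun (0.28, SE 0.07) among them, and 7 adjusted over the list alone (camera adjusted p = 0.000280, and adjusted p = 0.471 with an estimated correlation). Xenobiotic metabolism had 5 of 22, led by the monooxygenase Fmo2 at 450 ± 177 against 142 ± 19.3 CPM, and 5 adjusted over the list alone (camera adjusted p = 0.00219, and adjusted p = 0.323 with an estimated correlation).

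Camera ranked the cell cycle, pericyte and cholesterol lists lower after tamoxifen. All 27 cell cycle genes lay below 0 at a median of -0.28 (camera adjusted p = 4.73e-08, and adjusted p = 0.471 with an estimated correlation). Over all genes 0 fell, with Cdk1 at 76.3 ± 13.7 against 98.0 ± 10.5 CPM (edgeR adjusted p = 0.0606), and adjusted over the list alone 12 did. Of 12 pericyte genes 3 fell, and 4 adjusted over the list alone (camera adjusted p = 0.00422, and adjusted p = 0.178 with an estimated correlation), with Gucy1a3 at 485 ± 6.10 against 600 ± 13.9 CPM and Rgs5 at -0.59 (SE 0.15). In the cholesterol list, where 19 of 23 lay below 0, only the sterol carrier Stard4 fell (-0.30, SE 0.06), and 1 adjusted over the list alone (camera adjusted p = 0.00572, and adjusted p = 0.512 with an estimated correlation). Camera did not call the elastic fibre list (adjusted p = 0.114), though its members Fbn2 (-0.46, SE 0.10) and Fbln5 (-0.29, SE 0.06) fell. Among matrix proteases the aggrecanase Adamts5 fell (-0.80, SE 0.11), and among growth factor genes Gli1, a hedgehog target, and Fgfr3 rose by 0.55 (SE 0.08) and 0.36 (SE 0.06). Camera did not call the oestrogen-responsive list (adjusted p = 0.940), with 2 rises and 1 fall among 15 genes. The count of genes was 429 without tamoxifen replicate 1 and 1268 with the intronic share as a covariate.

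**Figure D5:**
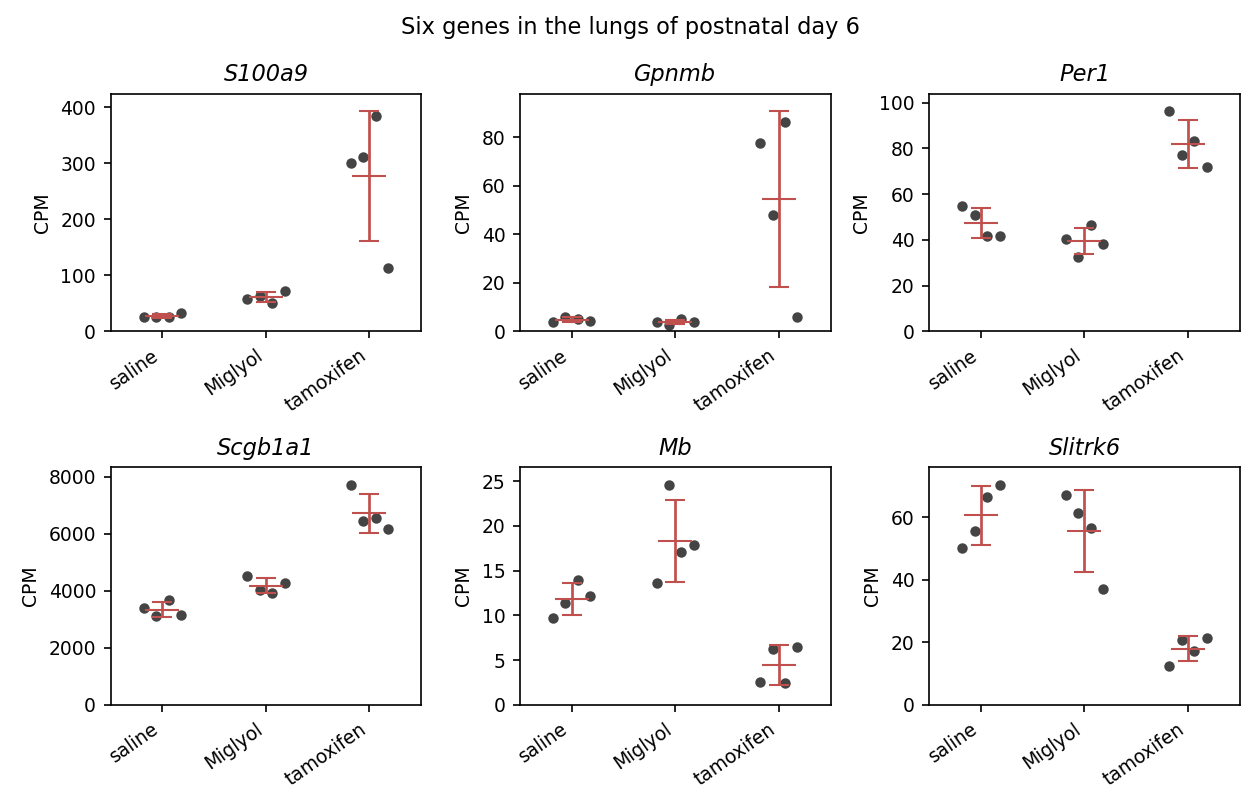
Normalised expression (y axis, CPM) of 6 genes in the 3 groups of postnatal day 6 (x axis), with each library as a dot and the mean and SD in red. S100a9, Gpnmb, Per1 and Scgb1a1 are highest and Mb and Slitrk6 lowest after tamoxifen, and the tamoxifen library lowest for S100a9 and Gpnmb is the same one.

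Tamoxifen in oil against saline, the sum of both steps, gave 3343 genes, 1601 higher and 1742 lower. All 11 neutrophil genes rose at a median of 3.16 (camera adjusted p = 1.33e-11, and adjusted p = 0.290 with an estimated correlation), and 11 adjusted over the list alone. Of 15 genes of club and secretory cells 9 rose at a median of 0.97, and 12 adjusted over the list alone (camera adjusted p = 1.13e-07, and adjusted p = 0.155 with an estimated correlation). Of 12 pericyte genes 8 fell and 1 rose, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.000114, and adjusted p = 0.155 with an estimated correlation). The count was 1991 without P6 saline replicate 4 and 1190 with the intronic share as a covariate.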

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

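The fits with Xist and without water replicate 3 were planned, but their use as tests of these patterns was chosen only after the results were seen, as were the length fit, all intronic fits and the condition on upper quartiles, which is stricter than the bound first written.

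The first pattern is the 30 genes lower in daily saline than in untreated lungs. With Xist as a covariate their median log2 fold change was -0.386, with an upper quartile of -0.330 and 19 of 30 past, which argues against the mix of sexes. The lower intronic read share of daily saline libraries stays open, and weakly so, since over 12 libraries of the other groups at day 14 the mean level of these genes went with it within groups at r = 0.677 (permutation p = 0.0390, and 0.0584 adjusted over 3 relations), at a rho of 0.608 (p = 0.0950, adjusted 0.142) and at r = 0.554 without the 2 farthest libraries. With that share as a covariate the median moved from -0.386 to -0.247 with a median SE of 0.0749 both times, so all 30 stayed lower and 0 stayed past because the difference shrank. The share may itself be an effect of the injections or of sample handling, and the design names daily saline as an untested biological cause.

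The second pattern is the change after Miglyol, 1498 genes. Once the trend with exon length of each library was removed, 18.9% of the calls stayed past the threshold. This argues against that trend as the whole cause, but not against a bias that exon length follows only in part. The median fall then moved from -0.337 to -0.174 (median SE 0.0823 and 0.0623) and the median rise from 0.335 to 0.183 (median SE 0.0912 and 0.0778). The smaller SE helps genes with smaller differences stay past. The lower intronic share of the Miglyol libraries stays open, since over 24 libraries outside the comparison the difference between rising and falling genes went with it at r = -0.696 (permutation p = 0.00256, adjusted 0.00768), at a rho of -0.713 and at r = -0.584 without the 2 farthest libraries. With the share as a covariate the medians were -0.207 (median SE 0.0824) and 0.221 (median SE 0.1003). Of the falls and rises 2 and 0 genes then stayed past, with smaller differences and, among the rises, also a larger SE than the 0.0912 without it. Ribosomal protein genes went from a median of 0.202 to -0.0103 with the share and -0.0281 with length, so that list may follow RNA or library quality, while an effect of the oil on the lung stays open and untested.

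The last pattern is the lower level of T and NK cell genes in daily saline than in water lungs, at a median of -0.483. In camera these genes also ranked higher in water than in untreated lungs, and their list was not called for daily saline against untreated. The difference may therefore lie, at least in part, with the water group. Without water replicate 3, which carried muscle, adipose and thymus genes, the median was -0.442 with an upper quartile of -0.329. This argues against tissue carried along in that library as the source, although 1 of 17 genes then stayed past where 4 had. Without that library and with Xist as a covariate the median was -0.333 with an upper quartile of -0.281, so both together stay open. Tissue carried along in other libraries was not tested. A lower intronic share is argued against by r = -0.265 over 12 libraries (permutation p = 0.376, so the sign is uncertain) together with a median of -0.780 (median SE 0.328, 17 of 17 lower, 0 past) once the share was a covariate. With Xist as a covariate the median was -0.433 with an upper quartile of -0.227, and the mix of sexes stays open because only 2 daily saline libraries were high in Y-linked genes as all 4 water libraries were, although both lay below all 4 in this list. The injections themselves stay open as an untested biological cause.

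The other splits of the 8 libraries of each comparison show which counts exceed them. The real split alone gave its count of genes (1 of 35) for daily saline against untreated, where the highest other count was 1, against water, where it was 0, for scrambled 1 against water, 1, and against untreated, 0, for Miglyol against saline, 0, tamoxifen against Miglyol, 203, and tamoxifen against saline, 1. For water against untreated 3 of 35 splits gave as many, the highest 124, and for scrambled 1 against scrambled 2 it was 2 of 35, the highest 600. For scrambled 2 the real counts were 0, so all 35 splits had to give as many and decide nothing. The highest gave 9 against water and 721 against untreated. The splits with 124, 600 and 721 genes exchange untreated replicate 4 with water replicate 3, scrambled 2 replicate 4 with scrambled 1 replicate 2, and untreated replicate 4 with scrambled 2 replicate 4, so they point to a structure of the samples that the labels do not give, and the labels were kept. Lists called were matched by other splits in every comparison: 35 of 35 splits had as many for daily saline against untreated (highest other 19), 7 for water against untreated (27), 11 for daily saline against water (26), 33 for scrambled 1 against water (21), 24 for scrambled 2 against water (26), 35 for the oligonucleotides (18), 21 and 13 for scrambled 1 and 2 against untreated (20 and 22), 6 for Miglyol (15), 5 for tamoxifen against Miglyol (20) and 6 for tamoxifen against saline (21).

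Between groups that serve as controls, 389 genes differed between daily saline and water lungs and 29 between the control oligonucleotides. Daily saline and water pups also differed in the number (13 and 2), volume (25 and 10 µl per g) and last day (13 and 3) of injections. In data outside the main measurement, the records without exon reads, 123 passed between daily saline and water, 112 between Miglyol and saline and 297 between tamoxifen and saline.

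Single libraries far from the other 3 of their group were singled out in 5 of 32 groups of library measures, 1 of 56 groups of list levels and 23 of 418 groups of gene values, where chance alone gives about 1 in 20. The unique share of exon reads was 90.5% in daily saline replicate 4 (others 90.2%) and 90.6% in water replicate 2 (others 90.3%). Exon reads (M) were 11.3 in P6 saline replicate 4 (others 8.01 to 8.05) and 12.443 in Miglyol replicate 1 (8.93 to 9.51), and the 10 genes with most reads took 6.33% in Miglyol replicate 4 (5.20% to 5.26%). The skeletal muscle list stood at 4.99 in water replicate 3. Untreated replicate 4 had Mdm4 at 332 CPM (others 258 to 265), Neurl3 at 18.0 (26.2 to 27.9), Ogt at 593 (495 to 509), Prpf39 at 124 (104 to 107) and Rnpc3 at 59.2 (50.2 to 51.5). In daily saline lungs Ager was 1629 in replicate 4 (1369 to 1409), Arntl 31.1 in replicate 1 (33.6 to 34.1), Igfbp5 904 in replicate 3 (736 to 752), Per2 44.1 in replicate 1 (49.5 to 50.2), Rnpc3 41.9 in replicate 4 (37.5 to 37.9) and Slfn3 28.5 in replicate 2 (22.4 to 22.9). In water lungs Flt4 was 67.3 in replicate 1 (69.7 to 70.1), and replicate 3 had Nox4 at 65.4 (74.5 to 75.6) and Ppargc1b at 12.8 (4.65 to 6.01). S100a9 was 33.0 in P6 saline replicate 4 (25.5 to 26.5). Among Miglyol libraries Ccr2 was 30.2 and Ifitm6 4.30 in replicate 2 (20.5 to 22.0 and 2.74 to 2.99), Lyz2 was 1504 in replicate 1 (1271 to 1307), and replicate 4 had Igfbp2 at 115 (84.9 to 88.8), Insig1 at 57.1 (67.3 to 68.8), Retnlg at 15.5 (11.0 to 11.7) and Rplp1 at 746 (602 to 611). Chil3 was 57.7 in tamoxifen replicate 1 (33.5 to 35.5).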

How the results depend on the processing

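Values with the intronic share as a covariate, with the length trend removed, and without water replicate 3 and with Xist were chosen after results were seen, as were the list tests with Xist. The tally of named genes holds 295 pairs of a gene and a main comparison, and those of scrambled 2 against water were not past to begin with. None turned direction under any alternative. RLE scaling lost 1, DESeq2 14, limma-voom 8, the replicate block 67 and the intronic share 151. Only the 8 samples compared lost 66, Xist 61, removal of the length trend 60, all 32 samples 52, all reads in genes 38 and unique reads 21. Of 87 list calls in the main comparisons RLE scaling lost 0, Xist 22 and turned 1, the intronic share lost 10 and turned 5, and the estimated correlation lost 87. Among calls that involve the library left out, 20 were lost, 2 turned and 30 kept without water replicate 3. With Xist too, 33 were lost, 3 turned and 16 kept. Without scrambled 2 replicate 4, 11 were lost and 2 kept. Any other single library lost at most 9. A count of 0 leaves changes unseen: edgeR found 74% of 100 simulated 1.5-fold changes for scrambled 2 against water, and the share could be lower with fewer changed genes. A fold threshold lowers counts by construction, and for the other changes below the cause was not tested.

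Genes past the threshold moved as follows. Daily saline against untreated, 33: DESeq2 114, limma-voom 118, all reads in genes 13, intronic share 0, length trend removed 58, at least 1.5-fold 0, only the 8 samples 75, all 32 samples 53, and 1 without daily saline replicate 1, 2 or 3 or untreated replicate 3 or 4 to 9 without untreated replicate 1, with 3 without daily saline replicate 4 and 6 without untreated replicate 2. Water against untreated, 7: DESeq2 23, Xist 0, intronic share 11, length 13, 1.5-fold 3, only 8 samples 1, without water replicate 3 and with Xist 0, and 1 without water replicate 1 to 9 without untreated replicate 4, with 4, 2 and 3 without untreated replicates 1, 2 and 3 and 3 and 2 without water replicates 2 and 3. Daily saline against water, 389: limma-voom 626, all reads in genes 1270 (628 higher), intronic share 13 (8 higher), 1.5-fold 49, and 28 without daily saline replicate 1 to 276 without water replicate 1, with 40, 167 and 154 without daily saline replicates 2, 3 and 4 and 112, 258 and 161 without water replicates 2, 3 and 4. Scrambled 1 against water, 17: DESeq2 98, limma-voom 28, Xist 2, all reads in genes 10, intronic share 30, length 31, 1.5-fold 4, and 3 without scrambled 1 replicate 4 to 39 without its replicate 2, with 9 and 4 without its replicates 1 and 3 and 6 and 7 without water replicates 2 and 4. Scrambled 2 against water, 0: DESeq2 5, and 1 without scrambled 2 replicate 4. Scrambled 1 against scrambled 2, 29: DESeq2 63, limma-voom 145, Xist 12, intronic share 64, length 44, 1.5-fold 5, only 8 samples 6, all 32 samples 17, and 0 without replicate 1 of either to 205 without scrambled 2 replicate 4, with 1 and 1 without scrambled 1 replicates 3 and 4 and 6 and 3 without scrambled 2 replicates 2 and 3. Scrambled 1 against untreated, 43: DESeq2 75, limma-voom 71, no filter 25, intronic share 70, 1.5-fold 10, only 8 samples 19, all 32 samples 28, and 6 without scrambled 1 replicate 3 to 35 without its replicate 4, with 12 and 22 without its replicates 1 and 2 and 13, 7, 21 and 18 without untreated replicates 1 to 4. Scrambled 2 against untreated, 0: DESeq2 4, limma-voom 1, all 32 samples 1, and 1 without replicate 4 of either group. Miglyol against saline, 1498: limma-voom 2798, intronic share 2, length 357, 1.5-fold 163, only 8 samples 2573, all 32 samples 2272, and 308 without P6 saline replicate 4 to 1729 without Miglyol replicate 2, with 562, 685 and 345 without Miglyol replicates 1, 3 and 4 and 748 and 490 without P6 saline replicates 2 and 3. Tamoxifen against Miglyol, 801: limma-voom 1310, intronic share 1268, 1.5-fold 299, only 8 samples 488, and 429 without tamoxifen replicate 1 to 1188 without its replicate 2, with 471 and 526 without Miglyol replicates 1 and 2. Tamoxifen against saline, 3343: intronic share 1190, 1.5-fold 803, and 1991 without P6 saline replicate 4 to 3924 without tamoxifen replicate 4.

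Lists that turned direction, with adjusted p: the list alveolar type 2 cells, water vs untreated, P14 without water replicate 2 (0.809, the lowest 8.69e-05 without water replicate 4), the list ciliated cells, water vs untreated, P14 with Xist (0.962), without untreated replicate 4 (0.917, the lowest 4.27e-05 without untreated replicate 1) and without water replicate 3 and with Xist (0.365), the list adipose tissue, water vs untreated, P14 without water replicate 3 (0.811, the lowest 0.000256 without water replicate 4) and with Xist too (0.463), and the list cytoplasmic ribosomal proteins, water vs untreated, P14 with the intronic share (0.895). With the intronic share also the list microRNA pathway, daily saline vs water, P14 (0.0793), the list alveolar type 2 cells, daily saline vs water, P14 (0.0256), the list cytoplasmic ribosomal proteins, daily saline vs water, P14 (8.35e-05) and the list cytoplasmic ribosomal proteins, Miglyol vs saline, P6 (0.684). The list skeletal muscle, scrambled 2 vs water, P14 did so without water replicate 3 (0.532, the lowest 0.000298 without water replicate 4) and with Xist too (0.609).

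The replicate numbers were not taken to pair the samples, since in no comparison made here were all 4 same-numbered pairs correlated over 0.1, though all 4 of daily saline and scrambled 1 were. The 40 such pairs at day 14 had a mean correlation of 0.0548 (18 over 0.1, and 30 of 120 other pairs, mean -0.0185), and the 12 at day 6 one of -0.0910 (3 over 0.1, and 13 of 36 others, mean 0.0304). With the replicate block, counts were 18 for scrambled 1 against scrambled 2 and 461 for Miglyol against saline, and 1 of 87 list calls was lost.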

Other observations

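The test of age below was planned before its result was seen, and the genes without exon reads were examined only as unused columns.

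Records without exon reads include long noncoding and immunoglobulin loci, and those named here were chosen after their values were seen. In daily saline against water lungs 123 of 1920 passed in edgeR, 9 higher and 114 lower. The reads of such records, from spliced transcripts or not, are counted only in the intron and gene columns. The intronic read share, taken over genes that have exon reads, was also lower there, at 10.0% against 14.1%. A link between the falls and that share was not tested. One of the falls was Meg3, an imprinted noncoding gene, at 138 ± 14.2 against 233 ± 51.6 CPM. Miglyol against saline gave 112 of 1846, with the snoRNA hosts Gas5 (0.42), Snhg5 (0.53) and Snhg3 (0.68) higher and Fendrr, a noncoding gene of lung mesenchyme, lower (-0.40). Tamoxifen against saline gave 297, with Neat1, the scaffold of paraspeckles, at 999 ± 112 against 503 ± 70.9 CPM, and tamoxifen against Miglyol gave 65, with the immunoglobulin heavy chain locus Igh higher (0.62). Igh was also higher in scrambled 1 than in scrambled 2 lungs, at 149 ± 15.5 against 98.5 ± 8.48 CPM.

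The lists of club cells and the cell cycle had medians of the same sign after tamoxifen as between day 6 and day 14, so it was asked whether tamoxifen lungs stand nearer the day 14 profile. The difference called age was that of untreated lungs at day 14 against saline lungs at day 6. Across 14107 genes, which are not independent replicates, the log2 fold changes of tamoxifen and of age correlated at r = 0.217. Of the 35 splits of the same 8 libraries 7 gave as much, the highest other 0.361. The test was negative. Of the 801 genes past the threshold 64.4% had the same sign, where 54.0% of all genes did. Medians for age and tamoxifen were 0.118 and 2.17 for neutrophils, 1.085 and 0.672 for club cells, 0.0497 and 0.242 for type 2 cells, 0.235 and 0.571 for glucocorticoid targets, -1.90 and -0.279 for the cell cycle and 0.0574 and -0.111 for pericytes. Age also came with another way of killing the animals, and only the day 6 pups of this comparison had been injected.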
